A study of Mus musculus with 2 samples.

How the data were processed

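Droplet single-cell RNA sequencing was done by the authors on cells of the RPE and choroid of C57BL/6J mice, with the eyes of 6 mice pooled per group. Per the labels, 1 group received NaIO3 at 20 mg/kg into a vein and the other PBS, and the treatment lasted 7 days. After digestion with dispase the anterior parts and the neural retina were removed, and brown hexagonal cells were collected under a microscope before droplets were made on the 10x Genomics platform. The deposited values are raw UMI counts per gene and barcode, with no normalisation. Per the submitters' processing notes the counts came from Cell Ranger 3.0.2 with the mm10 build. The annotation release, the strand setting, the handling of reads that match several genes and the cell calling settings are not given in the sources used here. Each matrix holds only barcodes called as cells, so the RNA of empty droplets could not be used. The matrices have 27998 gene rows, of which 27722 have an identifier in GENCODE M21, from which coordinates (GRCm38) were taken; 65 symbols stand on 2 rows and were told apart by identifier.

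The PBS library had 4618 barcodes, 51055592 UMIs and between 2979 and 63062 UMIs per barcode. The NaIO3 library had 4058 barcodes, 51168520 UMIs and between 4217 and 76174 UMIs per barcode. The median share of mitochondrial counts was 7.85% in PBS and 8.91% in NaIO3. Barcodes with at least 500 genes and at most 25% mitochondrial counts were kept, which removed 231 in PBS and 114 in NaIO3. Doublets were ranked per library with Scrublet as in scanpy, and the highest scores were removed up to a share of 0.8% for each 1000 barcodes in the library, 171 barcodes in PBS and 132 in NaIO3, since the automatic threshold marked only 0 and 7. This left 8030 cells.

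Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes (20 bins, expressed in at least 10 cells) were scaled with a limit of 10 standard deviations. Both libraries were clustered together without integration, on 30 principal components, 15 neighbours weighted by the Jaccard index of shared neighbours, and Leiden resolution 1 (5 iterations, seed 1), which gave 29 clusters. A cluster was named from marker genes of 26 cell classes. For each marker the log2 fold of the cluster's CPM (plus 5 CPM) over the median of all clusters was taken. A name needed a mean of at least 1 over its markers, at least 3 markers at 2-fold or more, and no other class with more markers among the 10 leading genes. A cluster whose median of UMIs was more than 3-fold below that of its library, with none of its markers among the leading genes, was not named. The names end in "-like" since they rest on markers alone. All samples were grouped by treatment.

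Counts were summed over the RPE-like cells of each library, 35750993 in PBS and 16181770 in NaIO3, and expressed as CPM. The design has 1 library per group, so no test, standard error or count of changed genes is given. Levels carry exact Poisson 95% intervals, ratios exact conditional binomial 95% intervals and shares of cells exact Clopper-Pearson 95% intervals. All of them cover counting error only. A share of 0 is given with the limit of 3 counts of the total in place of an interval. Ratios of list members used a pseudocount of 0.5. The rule for named genes ranked genes with at least 100 counts in 1 library by the bound of the ratio's interval nearest to 1 and took the first 15 higher and 15 lower. It left out mitochondrial, ribosomal protein, haemoglobin, predicted and Y-linked genes, Xist and Tsix, and 919 genes whose level was under 0.1 of that in another class or unnamed cluster (free RNA), so that 8614 genes could be ranked. The genes named for cluster 9, and Dcn, Pax6 and Spp1 as comparisons, were chosen after their values were seen or as members of a list.

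The 31 gene lists were fixed before the data were examined, as were the comparisons, filters, marker genes, rule for named genes and the larger part of the alternatives. They cover RPE function (visual cycle, melanin, transcription factors, outer segment uptake, lysosome, epithelial junction, channels), senescence (arrest, genes lost, secreted factors, p53 targets) and stress (NRF2 targets, metallothionein, iron, integrated stress, apoptosis, immediate early genes). They also cover inflammation (complement, interferon and MHC class I, MHC class II, cytokines, lipid-associated and resident macrophages), metabolism (mitochondrial genome, nuclear oxidative phosphorylation, glycolysis, lipid), and mesenchymal, growth factor, cell division and choriocapillaris genes. Of the 577 genes in lists and markers, 568 matched a row. Members with a summed count of at least 20 were used. The percentile of a list's median is its place among 10000 random lists of the same size, matched in 20 bins of mean expression (1000 random lists for subclusters).

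RPE-like cells were clustered again at Leiden resolution 0.5 on variable genes without the senescence and p53 lists. Shares of cells with a Cdkn1a or Cdkn2a UMI were taken after thinning each cell to 5637 UMIs, the 10th percentile of NaIO3 RPE-like cells, and cells with fewer were left out (282 in PBS and 127 in NaIO3 RPE-like cells). Cluster 9 was clustered again without the 79 genes of 4 lists and without the 131 genes of 8 lists; only lists left out of that clustering are reported for it. The interferon-led cluster was looked for again in clusterings without the 20 genes of its list and without 30 genes.

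The procedure was tested on simulated data, made by drawing counts from the measured levels with known folds. The 95% interval of the ratio covered the true value in 95.8% of 13377 unchanged genes and in 94% of 50 genes set to 1.5-fold. A list of 20 genes shifted by 2 on the log2 scale was found at 1.99, and an unshifted list of 19 genes at 0.02.

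The alternatives fixed at that time were a mitochondrial limit of 10% or none, at least 1000 genes per cell, no doublet removal, Leiden resolution 0.5, each library clustered alone, TMM scaling, and CPM without mitochondrial, ribosomal protein and haemoglobin genes. Further ones were the mean over cells, thinned cells, free RNA removed with a share from rod genes, the largest RPE-like cluster alone, members with at least 100 counts, the ratio of summed counts, other subcluster settings and other thinning. Added after the data were seen were the pigment-led clusters counted as RPE-like, free RNA removed with a share from surface epithelium and macrophage genes, members at the free RNA level left out, leaving out the interferon-led cluster, and all alternatives for the lists of cluster 9. Agreement of the pigment-led clusters was set against 1000 Poisson draws from the rate of both libraries together.

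The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors. Classes other than RPE-like were not compared gene by gene, since none had at least 100 cells in each library in the clustering used here.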

Results

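The data are single-cell RNA counts from the retinal pigment epithelium (RPE) and choroid of C57BL/6J mice, the pigmented layer behind the photoreceptors and the vascular layer under it. Sodium iodate (NaIO3), an oxidant that damages the RPE, was injected into a vein at 20 mg/kg, and control mice received phosphate-buffered saline (PBS). Eyes were taken 7 days later, the eyes of 6 mice were pooled per group, and each pool gave 1 droplet library, so there are no replicates and no difference given here has a replicate check. Cells reached the droplets after removal of the neural retina and collection of brown hexagonal cells by hand, so the mix of cells reflects that dissection as well as the eye. The PBS library holds 4618 barcodes and 51055592 unique molecular identifiers (UMIs), with a median of 10024.5 UMIs per barcode. The NaIO3 library holds 4058 barcodes and 51168520 UMIs, with a median of 9792.5. After filtering, 4217 PBS cells and 3813 NaIO3 cells were kept. Intervals are exact 95% intervals that cover counting error only.

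What mix of cells each library held was asked with 29 clusters named by marker genes. Cells with the visual cycle genes of RPE made up most of the PBS library and a smaller part of the NaIO3 library, where surface epithelium-like cells, macrophage-like cells and a cluster found almost only in that library took larger shares. RPE-like cells (clusters 1, 2 and 10 in PBS and 4, 6 and 15 in NaIO3) were 66.2% of PBS cells (64.8 to 67.7, Clopper-Pearson) and 33.2% of NaIO3 cells (31.7 to 34.7). These shares depend on the clustering: at Leiden resolution 0.5 they were 81.1% and 19.7%, and over 7 alternatives they ran from 54.2% to 81.1% and from 19.7% to 56.4%. Each of these clusters came from 1 library but for 2 NaIO3 cells in cluster 10, so a split between them may be the library and not a cell type. Clusters 5 (PBS) and 3 (NaIO3) carried the same RPE markers, but melanocyte markers such as Pmel, Dct, Mlana and Tyrp1, which both pigment cell types express, led them. By the naming rule they stayed unnamed, and they held 14.8% of PBS cells (13.8 to 15.9) and 23.2% of NaIO3 cells (21.9 to 24.6). RPE-like and pigment-led clusters together came to 81.1% and 56.4%.

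Of the cells that were not RPE-like, surface epithelium-like cells made up 1.90% of PBS cells (1.51 to 2.36) and 18.2% of NaIO3 cells (17.0 to 19.5). Macrophage-like cells made up 0.711% (0.481 to 1.01) and 11.99% (11.0 to 13.1). The PBS number depends on the clustering, with 30 cells here, 104 at Leiden resolution 0.5 and 102 with each library clustered alone. Cluster 17, with 74 PBS and 19 NaIO3 cells, carried macrophage markers but had more dendritic markers among its leading genes and stayed unnamed. Fibroblast-like cells were 5.72% and 0.970%, and mural-like cells, which wrap vessels, were 1.64% and 0.0525%. Fibroblast-like cells numbered 241 and 37 here but 321 and 137 with each library clustered alone, so the size of their difference depends on the clustering. Rod-like cells were 1.68% and 0.682%, and Muller glia-like cells 0.0711% and 1.18%. The direction for rod-like cells depends on the clustering, with 71 PBS and 26 NaIO3 cells here and 38 and 48 with each library clustered alone. Cluster 9, unnamed by the marker rule, held 1 PBS cell and 271 NaIO3 cells, or 7.11% of that library (6.31 to 7.97), and 4.64% with each library clustered alone. Its highest class was mural (mean log2 fold 1.55), but more fibroblast markers were among its leading genes. In the setting with each library clustered alone 128 PBS and 177 NaIO3 cells were named melanocyte-like. The best match of cluster 9 there, at 4.64% of 3813 NaIO3 cells, had the same size as these 177. The naming rule may thus have called it melanocyte-like, but the overlap of cells was not tested. Cluster 9 is a cluster of 1 library and is described further on.

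**Figure D1:**
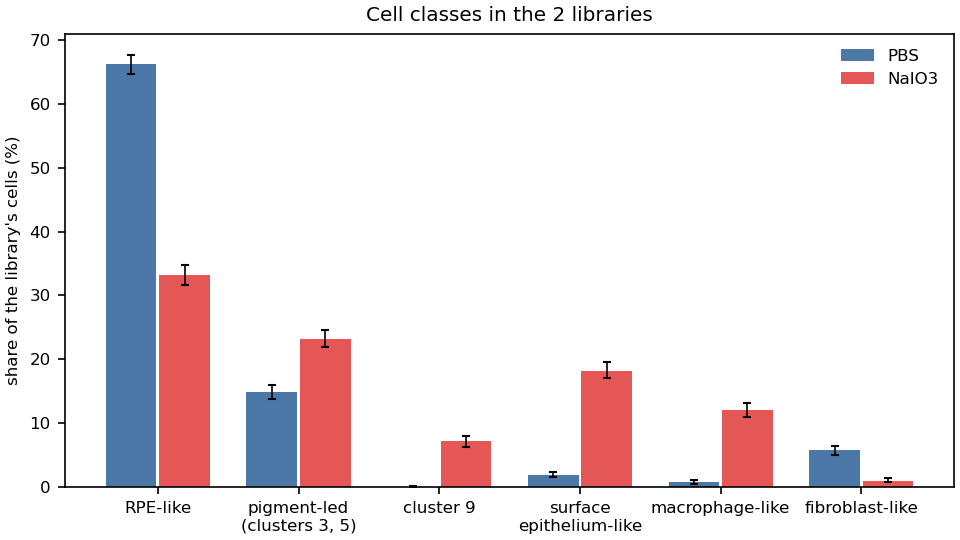
Share of kept cells (%) per library for RPE-like cells, the clusters led by pigment genes, cluster 9 and 3 other classes; bars are shares and lines are exact 95% intervals for counting error. RPE-like cells are 66.2% of the PBS library and 33.2% of the NaIO3 library.

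The main comparison set RPE-like cells of the NaIO3 library against those of the PBS library, to see what the epithelium that remained after the oxidant expressed. Among single genes, the highest ratios by the fixed ranking rule were genes induced by interferon. Ifit1, which encodes a protein that binds foreign RNA (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009, GRCm38), was at 2.43 CPM (UMI counts scaled to the same total in each library) in PBS and 205 in NaIO3, a ratio of 84.2 (68.0 to 105). Rsad2 (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452), which encodes the antiviral enzyme viperin, was at 0.392 and 37.6 CPM, a ratio of 96.0 (56.7 to 177). Irf7, a transcription factor that amplifies the interferon response, was at 3.13 and 38.1 CPM, a ratio of 12.2 (9.94 to 15.02). Mx1 had only 3 UMIs in PBS and a ratio of 129 (43.4 to 631). The rule named 15 such genes, and the others were Iigp1, Cxcl10, Usp18, Ifit3, Parp14, Cmpk2, Trim30a, Tap1, Ddx60, Ifit3b and Ube2l6, with ratios from 5.98 for Ifit3b to 65.8 for Cxcl10. Ifit1, Ifit3 and Ifit3b are close paralogs, and how reads that match several of them were counted is not stated, so their separate values are uncertain.

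For Ifit1, Ifit3 and Rsad2 the higher level lay mainly in a small cluster, while the counts of some other interferon genes were more spread. Cluster 15, with 104 NaIO3 cells, was led by Ifit1, Rsad2 and Ifit3, and held Ifit1 at 2242 CPM (2163 to 2323), Ifit3 at 2224 CPM and Rsad2 at 420 CPM. The other NaIO3 RPE-like cells held Ifit1 at 17.4 CPM, Ifit3 at 44.7 CPM and Rsad2 at 2.43 CPM. Those levels are 13.8%, 34.3% and 13.2% of the mean over the whole NaIO3 library, while genes of surface epithelium, which RPE should lack, were at 15.5%. Of the Tap1 counts, 81 lay in cluster 15 and 110 in the other NaIO3 RPE-like cells, and Irf7 was at 15.05 CPM in those other cells against 3.13 CPM in PBS. Since cluster 15 was formed on such genes, the cells were clustered again without the 20 genes of the interferon list, and 80 of its 104 cells formed a cluster with 0 other cells, with Ifit1 at 2761 CPM. Without the named higher genes as well, 30 genes in all, it did not form again, and 61 of its cells lay in a cluster of 659.

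Among the genes with the lowest ratios, Ramp2, a partner of the receptor for adrenomedullin (ENSMUSG00000001240, chromosome 11, 101246028 to 101259546), was at 357 CPM in PBS and 117 in NaIO3, a ratio of 0.327 (0.312 to 0.344). Nog, which encodes the BMP antagonist noggin (ENSMUSG00000048616, chromosome 11, 89300638 to 89302332), was at 147 and 48.3 CPM, a ratio of 0.329 (0.305 to 0.355). Ciart, a repressor in the circadian clock, was at 22.0 and 7.11 CPM, a ratio of 0.322. The neuropeptide gene Nmb was at 39.9 and 14.8 CPM, and the neurotrophin gene Bdnf at 36.8 and 17.9 CPM. The other named genes were Il1rapl1 (ratio 0.268, 0.149 to 0.451), Tmem232, Igf2bp3, Nuak2, Lgi1, Serpine3, Folr1, Cirbp, Myl4 and the antisense RNA gene RP23-60P18.10. The last has a ratio of 0.458 that is uncertain, since whether the counting kept strands apart is not stated. Lgi1 and Serpine3 were higher in NaIO3 in some settings. Comparing only the largest RPE-like cluster of each library gave log2 ratios of 0.13 for Lgi1 and 0.88 for Serpine3. Serpine3 was at 1.40 with a mitochondrial limit of 10% and at 0.72 with the pigment-led clusters counted in.

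The fixed gene lists describe these cells more broadly. RPE-like cells of the NaIO3 library held the transcription factor and visual cycle genes of RPE at medians near their PBS levels, and more RNA for lysosomal, outer segment uptake, endoplasmic reticulum stress and lipid genes. The median log2 ratio of all 13577 measured genes was 0.18, and it was -0.01 with TMM scaling, so list values are read against that shift and against 10000 random lists matched on expression; the percentile describes these libraries and is no test. RNA from broken cells reaches every droplet, so a member was counted as at the free RNA level when its RPE-like level was under 0.1 of the highest level in another group of cells.

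The visual cycle list, the genes that recycle retinal for the photoreceptors, had a median of -0.10 (percentile 23.0), with 5 of 12 members above a ratio of 1. Within it Ttr, the carrier of thyroxine and retinol-binding protein, was at 93148 CPM in PBS and 60793 in NaIO3, and Rpe65, the isomerase of the cycle, at 4065 and 3559. The list was above 0 in 2 of 18 alternatives, both corrections for free RNA. RPE transcription factors were at -0.10 (percentile 13.5), with 1 of 6 members above 1 and Otx2, a factor that keeps RPE identity, at 351 and 334 CPM. The melanin list was at 0.34 (percentile 96.5), with 10 of 13 members above 1. RPE channels and transporters were at 0.14 (percentile 88.6, 8 of 14 above 1) and lay below 0 in 3 of 17 alternatives other than TMM scaling, which shifts all genes alike. Epithelial junction and keratin genes were at 0.31 (percentile 90.03, 9 of 10 above 1).

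All 15 lysosomal genes had a ratio above 1, with a median of 0.67 (percentile 100), and the protease gene Ctsd was at 2058 CPM in PBS and 4150 in NaIO3. Outer segment uptake genes, which serve the daily engulfment of photoreceptor tips, were at 1.01 (percentile 100, 9 of 10 above 1). They were at 0.62 without 3 members at the free RNA level and at 0.45 for the summed counts of all members. Gas6, a ligand for the uptake receptor, was at 51.5 and 119 CPM, whereas the receptor gene Mertk had a log2 ratio of -0.37. The integrated stress and unfolded protein response was at 0.79 (percentile 100, 15 of 18 above 1). There the endoplasmic reticulum chaperones Calr (185 and 384 CPM) and Hsp90b1 (162 and 303 CPM) and the serine synthesis enzyme Phgdh (426 and 665 CPM) were higher in NaIO3. The median mitochondrial share of RPE-like cells was 8.16% in PBS and 11.05% in NaIO3. With a mitochondrial limit of 10% the medians of the integrated stress and lysosomal lists were lower. Lipid and cholesterol genes were at 0.57 (percentile 99.98, 15 of 17 above 1), with Apoe at 8524 and 12646 CPM. These directions do not hold under every correction for free RNA. The share taken from rod genes removed 74.2% of PBS and 71.6% of NaIO3 counts, far above 9.88% and 16.8% from surface epithelium and macrophage genes. With this rod share lysosomal genes were at -4.10, integrated stress at -0.31 and lipid genes at -1.69. With the share from surface epithelium and macrophage genes lysosomal genes were at 0.33, and 0.54 without the 4 of 15 members at the free RNA level.

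Oxidative stress genes under the factor NRF2 had a median of 0.31 (percentile 98.1, 14 of 17 above 1). Among them Hmox1, the haem-degrading enzyme, was at 7.64 and 26.1 CPM. The 3 metallothionein genes were at 0.46 (percentile 97.6), with Mt1 at 13372 and 18376 CPM and Mt3 below a ratio of 1. Iron and ferroptosis genes were at 0.23 (percentile 77.3, 10 of 13 above 1), apoptosis genes at 0.58 (percentile 98.5, 10 of 11; -5.91 after the rod gene correction) and mitochondrial genome genes at 0.25 (percentile 99.0, 11 of 13). Nuclear oxidative phosphorylation genes were at -0.04 (percentile 37.2, 6 of 19) and above 0 in 3 of 18 alternatives. Glycolysis and hypoxia genes were at 0.11 (percentile 67.3, 13 of 17) and lay below 0 in 3 of 17 alternatives other than TMM scaling. The interferon response and MHC class I list had a median of 2.44 (percentile 100, 20 of 20 above 1), and 2.20 without 9 members at the free RNA level. It was at 1.95 without the interferon-led cluster, 1.75 in the largest cluster alone and 1.15 for the summed counts of all members.

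Several lists are carried by genes that other cells express far more strongly. Senescence arrest genes were at 1.61 (percentile 100, 11 of 12 above 1), but 7 members were at the free RNA level and the rest had a median of 0.24. The 32 secreted factors of senescence were at 1.41 (percentile 100, 27 above 1) and at 1.12 without 24 such members, among them Spp1, at 1302 CPM in RPE-like cells and 51259 CPM in macrophage-like cells. The p53 target list was at 0.50 (percentile 99.5, 22 of 23 above 1) and at 0.45 without 9 members. Genes lost in senescence, which would be lower in senescent cells, were at 0.26 (percentile 64.4, 6 of 8 above 1). Mesenchymal and wound genes were at 0.93 (percentile 100) and at -0.01 without 16 of 19 members. Immediate early genes, which dissociation also induces, were at 1.92 (percentile 100) and rest on 16 of 17 members at the free RNA level. The rod gene correction put arrest genes at -1.08, p53 targets at -0.79 and mesenchymal genes at -1.88.

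The remaining lists belong mostly to other cells. Cytokines and chemokines were at 1.84 (percentile 100, 11 of 14 members at the free RNA level), and cell division genes at 1.20 (percentile 99.8, 13 of 15; -0.10 after the rod gene correction). Lipid-associated macrophage genes were at 2.86 (percentile 100, 10 of 13), 0.57 without those members and -1.69 after the rod gene correction. Resident microglia genes were at 1.40 (percentile 98.8, 5 of 6) and complement genes at 0.23 (percentile 65.1, 6 of 12). Growth and angiogenic factors were at 0.28 (percentile 83.3, 6 of 12) and at 0.01 without those members. All 5 MHC class II genes (median 0.43, percentile 79.5) and all 8 choriocapillaris genes (0.27, percentile 50.3) were at the free RNA level.

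**Figure D2:**
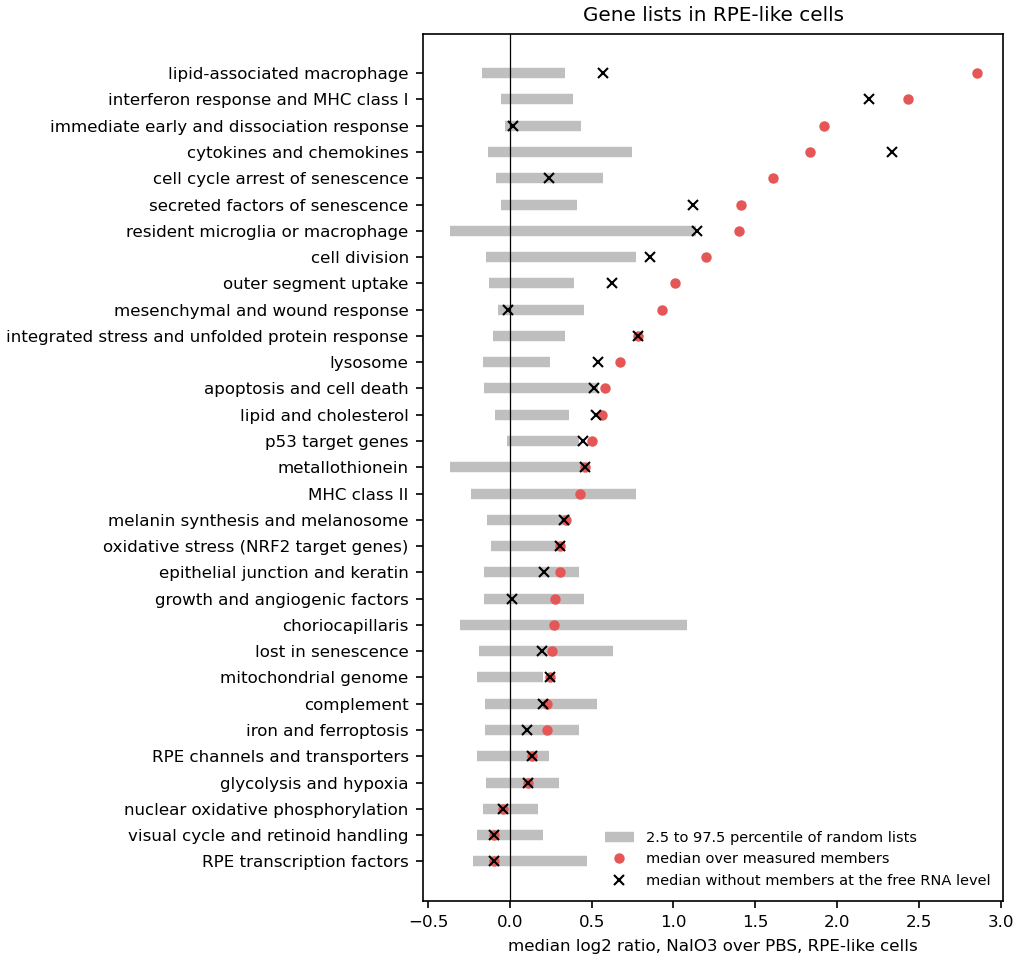
Median log2 ratio of NaIO3 to PBS in RPE-like cells for each gene list (points), the median without members at the free RNA level (crosses) and the range that holds 95% of the random lists (grey). Interferon genes stay at 2.20 without those members, while senescence arrest genes go from 1.61 to 0.24.

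Whether the same differences appear in the clusters led by pigment genes was looked at in NaIO3 cluster 3 and PBS cluster 5. Of the 30 named genes, 20 had an interval of the ratio on the same side of 1 as in RPE-like cells. The intervals of the other 10 (Mx1, Iigp1, Usp18, Ifit3, Parp14, Cmpk2, Trim30a, Ddx60, Ifit3b and Serpine3) included 1. Draws with no change in the pigment-led clusters gave a mean of 0.6 and at most 4 of 30, for counting error only. Of the 6 agreeing genes that were higher, 4 (Ifit1, Rsad2, Cxcl10 and Tap1) were at the free RNA level there, so their agreement can come from free RNA, and of the 14 that were lower 0 were. Both comparisons share the same 2 libraries and their free RNA. Lysosomal genes had a median of 0.42 there and outer segment uptake genes 0.76, and Ramp2 (0.387), Nog (0.421) and Ciart (0.317) were again lower. The interferon list was at 1.23 there but at 0.31 without 12 of 20 members at the free RNA level. Melanin genes were at -0.06 and channels at -0.08, on the other side of 0 from RPE-like cells. Senescence arrest genes were at 0.41 (percentile 92.4). Ifit1 was at 8.18 and 18.8 CPM, Ifit3 had a ratio of 1.10, and Serpine3 was at 1173 and 1158 CPM.

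The series title speaks of an RPE subset in senescence, so RPE-like cells were clustered again on genes without the 4 senescence and p53 lists. The subclusters split by library. Within the NaIO3 library none held Cdkn2a far above the others. The NaIO3 cells formed subcluster 2 (48.0% of NaIO3 RPE-like cells, 45.2 to 50.8), subcluster 3 (45.5%) and subcluster 8 (6.25%, 4.98 to 7.72), the last led by Iigp1, Rsad2 and Cxcl10. Senescence arrest genes had a median log2 ratio to the other NaIO3 RPE-like cells of -0.38, 0.44 and -0.03 in these subclusters, at percentiles 64.1, 48.2 and 49.3 of random lists, so they followed the other genes. P53 targets were at -0.41, 0.29 and 0.03 (percentiles 60.4, 14.9 and 67.7). Secreted factors were at -0.64, 0.55 and 0.11, at percentiles 0.5, 94.95 and 90. Median depths were 13563, 8141.5 and 10714 UMIs. Cdkn1a was at 38.6, 48.2 and 52.9 CPM, and Cdkn2a at 9.23, 9.35 and 6.61 CPM. Interferon genes were at 2.74 in subcluster 8. Among PBS cells, 50.9% were in subcluster 1.

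Cdkn1a and Cdkn2a encode inhibitors of cyclin-dependent kinases that mark arrested cells, and UMI counts per gene do not separate the transcripts of Cdkn2a. Both were found in more RPE-like cells of the NaIO3 library than of the PBS library, and other classes of the NaIO3 library held them as well. After thinning each cell to 5637 UMIs, Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727) had a UMI in 2.43% of PBS RPE-like cells (1.86 to 3.11) and 21.9% of NaIO3 RPE-like cells (19.5 to 24.4). Of NaIO3 rod-like cells, which do not divide and are few, 6 of 22 had a Cdkn1a UMI (27.3%, 10.7 to 50.2), at a median depth of 9740.5 UMIs. Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653) had a UMI in 0 of 2511 PBS cells, which allows a share of up to 0.119%, and in 5.45% of NaIO3 cells (4.20 to 6.93; 62 of 1138). In the same library Cdkn2a had a UMI in 7.60% of macrophage-like cells (5.26 to 10.6) and 7.06% of surface epithelium-like cells (5.09 to 9.48), but in 0 of 22 rod-like and 0 of 20 fibroblast-like cells, which allows up to 13.6% and 15%. The median depths before thinning were 10310 UMIs in NaIO3 RPE-like cells, 11905 in macrophage-like cells and 9085 in surface epithelium-like cells. In summed counts Cdkn2a was at 0 CPM in PBS and 9.15 CPM in NaIO3 (7.73 to 10.7), and the exact interval of the ratio begins at 87.5. It was at 4.14 CPM in NaIO3 rod-like cells, from 1 UMI (0.105 to 23.1). Cdkn1a was at 5.43 and 42.6 CPM in RPE-like cells, and in the NaIO3 library at 157 CPM in macrophage-like and 702 CPM in surface epithelium-like cells. In cluster 9, 80.5% of cells had a Cdkn1a UMI (75.2 to 85.2) and 55.7% a Cdkn2a UMI (49.5 to 61.8). For Cdkn2a no other group of this library in the plot was as high. For Cdkn1a the interval overlapped that of surface epithelium-like cells (83.8%, 80.5 to 86.7).

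Cluster 9 was looked at in detail after its Cdkn2a level was seen. It held cells with pigment genes, high levels of senescence, p53 and matrix genes and little visual cycle RNA, in the NaIO3 library but for 1 cell. Since clustering on such genes would by itself give high values for them, the cells were clustered again without the 131 genes of 8 lists. A cluster of 270 NaIO3 cells and 0 of 4217 PBS cells (which allows up to 0.0711%) formed again, with 267 of the 271 cells, and was 7.08% of the NaIO3 library (6.29 to 7.94). Its median depth was 24232 UMIs against 10310 in RPE-like cells. The values that follow compare this cluster with the NaIO3 RPE-like cells and cover the 8 lists that were left out.

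In that cluster the arrest list had a median log2 ratio of 1.33 (percentile 99.97, 11 of 12 above 1). Cdkn1a was at 839 CPM against 42.7, a ratio of 19.6 (18.2 to 21.3). Cdkn2a was at 413 CPM against 9.16, a ratio of 45.1 (38.2 to 53.5), and its neighbour Cdkn2b (ENSMUSG00000073802, chromosome 4, 89306299 to 89311039) at 321 against 7.42 CPM. The p53 target list was at 2.15 (percentile 100, 22 of 25), with the apoptosis gene Bax 4.43-fold higher. The secreted list was at 2.21 (percentile 100, 29 of 33), with the protease inhibitor Timp1 at 334 against 11.0 CPM, while Vegfa was lower at a ratio of 0.224. Genes lost in senescence were at -0.02 (percentile 23.7), with 4 of 8 on each side, and above 0 in 3 of 7 alternatives. The mesenchymal list was at 3.31 (percentile 100), with 20 of 20 members above 1. Fibronectin (Fn1) was at 942 against 22.2 CPM, collagen Col1a1 at 564 against 10.3 CPM and vimentin (Vim) at 1051 against 47.8 CPM.

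The visual cycle list was at -2.28 (percentile 0), with 0 of 12 members above 1. Rpe65 was at 414 CPM against 3562, and at 268 CPM in macrophage-like cells, which should lack it. RPE transcription factors had a median of -0.07 (percentile 19.9), which was above 0 in 4 of 7 alternatives. Otx2 was at 227 against 334 CPM and Mitf, the factor for pigment genes, at 101 against 74.3 CPM. Pax6, a factor of early eye and ciliary epithelium, was at 111 against 11.6 CPM. The second value is at the free RNA level, since surface epithelium-like cells held Pax6 at 3545% of it. The melanin list was at 0.53 (percentile 85.1), with 9 of 13 members above 1 and Mlana at 241 against 73.4 CPM. That list was below 0 in 1 of 7 alternatives, at -0.24 with the NaIO3 cluster led by pigment genes as the comparison in place of RPE-like cells. Dcn, an abundant fibroblast transcript, was at 19.2 CPM against 11178 CPM in the fibroblast-like cells of the library.

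**Figure D3:**
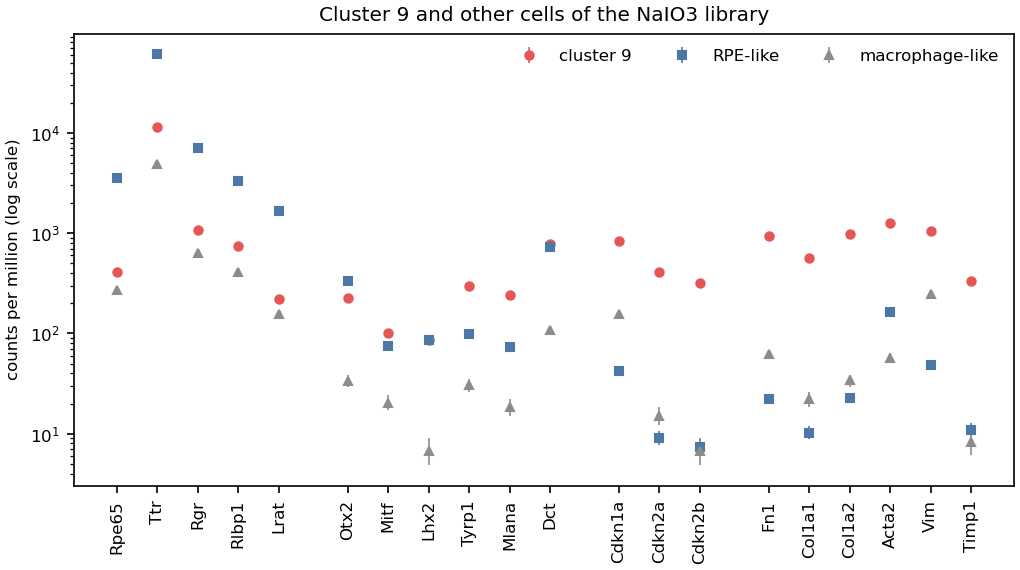
Level (CPM, log axis) of 20 genes in the NaIO3 library in cluster 9, RPE-like cells and macrophage-like cells. Cdkn2a, at 412 CPM in cluster 9 as first formed, is at 9.15 CPM in RPE-like and 14.97 CPM in macrophage-like cells.

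No other named class had at least 100 cells in each library, the minimum fixed in advance, so none was compared gene by gene. This depends on the settings. At Leiden resolution 0.5 macrophage-like cells (104 and 476) and surface epithelium-like cells (101 and 700) reached the minimum, and without a mitochondrial limit surface epithelium-like cells did (101 and 720). With each library clustered alone fibroblast-like (321 and 137), melanocyte-like (128 and 177), macrophage-like (102 and 475) and surface epithelium-like cells (101 and 585) did. In the clustering used here macrophage-like cells numbered 30 in PBS and 457 in NaIO3, and surface epithelium-like cells 80 and 695.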

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

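Chosen only after the results were seen were the alternatives that counted the pigment-led clusters as RPE-like, removed free RNA with a share from surface epithelium and macrophage genes, left out members at the free RNA level or left out the interferon-led cluster, and all alternatives for the lists of cluster 9. No paired analysis was possible because the groups share only replicate number 1. Other classes were not compared with TMM scaling or without doublet removal, since no class had enough cells in both libraries in the clustering used here. With 1 library per group no replicate was left out. Depth limits how low a Cdkn2a level the 0 counts of PBS RPE-like cells can exclude. Those cells were deeper than the NaIO3 RPE-like cells, with medians of 11655 and 10310 UMIs.

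Of 548 list medians under the alternatives, 346 stayed within the counting interval of their value, 191 moved and 11 reversed. Reversed is counted here only for lists whose own median lay outside the middle 95% of random lists, and 33 of the 548 values had the other sign, 14 of them with free RNA removed by rod genes and 2 with TMM scaling, which shifts all genes alike. Of 446 ratios of named genes, 332 stayed within counting error, 110 moved and 4 reversed. Of 56 medians for cluster 9, 37 stayed and 19 moved, and 8 had the other sign, all in the lists of genes lost in senescence, RPE transcription factors and melanin, whose medians lay within the middle 95% of random lists. Of 35 shares, 19 stayed and 16 moved. The interferon list kept its direction in 18 of 18 alternatives (1.15 to 2.64), as did outer segment uptake (0.45 to 1.15) and secreted factors (0.75 to 1.44). In the text that follows, medians are log2 ratios in RPE-like cells, and the cause was not tested unless it is given.

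With a mitochondrial limit of 10% RPE-like shares were 54.2% in PBS and 28.1% in NaIO3, visual cycle genes -0.032, lysosome 0.50, integrated stress 0.57, interferon 2.21, visual cycle genes in cluster 9 -2.86, the PBS share with Cdkn1a 3.15% and Serpine3 1.40. Without a mitochondrial limit the PBS share was 70.2%. At Leiden resolution 0.5 the shares were 81.1% and 19.7%, lysosome 0.42 and integrated stress 0.40. With each library clustered alone the PBS share was 58%, cluster 9 4.64%, visual cycle genes -0.12 and lysosome 0.76, and in cluster 9 the arrest list was 0.95 and the visual cycle list -1.79. Counting the pigment-led clusters in, which adds their cells by construction, gave 81.1% and 56.4%, visual cycle genes -0.15 and Serpine3 0.72.

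TMM scaling gave visual cycle genes -0.29, lysosome 0.48, integrated stress 0.60 and interferon 2.25. Without mitochondrial, ribosomal protein and haemoglobin genes visual cycle genes were at -0.072. The mean over cells gave visual cycle genes -0.16 and lysosome 0.75. Thinned cells gave -0.13 and 0.72, and -2.13 for visual cycle genes in cluster 9. The largest RPE-like cluster alone gave visual cycle genes -0.11, lysosome 0.43, secreted factors 1.05, integrated stress 0.59, interferon 1.75, Lgi1 0.13 and Serpine3 0.88. Without the interferon-led cluster the interferon list was at 1.95. Members with at least 100 counts gave 0.56 for arrest and 0.84 for secreted factors. The ratio of summed counts, which abundant members decide by construction, gave visual cycle genes -0.47, lysosome 0.74, arrest 0.76 and interferon 1.15.

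Removing free RNA with the share from rod genes took 74.2% of the PBS counts and 71.6% of the NaIO3 counts, far above the 9.88% and 16.8% from surface epithelium and macrophage genes. By its construction it sets genes to near 0 wherever that share exceeds their count. It gave visual cycle genes 0.29, lysosome -4.10, arrest -1.08, secreted factors 1.05, integrated stress -0.31, p53 targets -0.79, mesenchymal genes -1.88, cell division -0.10, lipid genes -1.69, apoptosis -5.91 and lipid-associated macrophage genes -1.69. With the share from surface epithelium and macrophage genes visual cycle genes were at 0.0054, lysosome 0.33, arrest 0.19, secreted factors 0.75 and mesenchymal genes -1.60, and in cluster 9 the arrest list was 2.05 and the visual cycle list -3.09. Without members at the free RNA level, which leaves fewer genes, lysosome was at 0.54, arrest 0.24, secreted factors 1.12, interferon 2.20 and mesenchymal genes -0.013.

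Without thinning, Cdkn1a had a UMI in 5.23% of PBS and 39.9% of NaIO3 RPE-like cells and Cdkn2a in 11.2% of NaIO3 cells, and after thinning to 10310 UMIs in 4.62%, 33.8% and 7.27%. Deeper cells show more UMIs by construction.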

Other observations

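All tests in this part were chosen only after the results were seen, on the same cells.

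A hypothesis from these data is that part of the pigment epithelium of NaIO3-treated eyes lost its visual cycle RNA and took on senescence, p53 and matrix genes while it kept pigment cell genes. Cluster 9 shows that profile, and several technical sources were tested. Choroidal fibroblasts would bring all their abundant transcripts, but 5 of their markers other than collagen I stood at a median of 0.978% of fibroblast-like cells, while Col1a1 and Col1a2 stood at 105% and 116%, which argues against them. Mural cells like those of the PBS library would bring theirs too, but the 4 mural markers of at least 1000 CPM there stood at a median of 3.32% of that level, with Rgs5 at 0.152%, Myh11 at 0.085%, Tagln at 6.50% and Acta2 at 11.65%, which argues against them although the weaker Pdgfrb and Cspg4 stood at 48.9% and 66.4%. Free RNA of RPE-like cells would leave pigment genes at a low level as in macrophage-like and surface epithelium-like cells (25.04% and 28.0% of RPE-like cells), but 19 such genes had a median of 134%. Joined droplets of an RPE-like cell and another cell would need RPE genes at 42.6% of the RPE-like level from the depths of both, and 6 such genes stood at 18.7% (upper bound 18.8), against 8.36% in macrophage-like cells.

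What stays open for cluster 9 is which cell type its cells were and where they lay in the eye. The NaIO3 library held 2 mural-like cells, so mural cells changed by NaIO3 could not be used as a comparison. Cluster 9 held Pax6 at 9.54-fold the level of RPE-like cells (111 against 11.6 CPM). Surface epithelium-like cells held it at 3545% of the RPE-like level, so the RPE-like value is at the free RNA level by the rule used here. Pax6 is high in the pigmented epithelium of the iris and ciliary body. Of the markers fixed for that epithelium, Col18a1 was at 230.3 against 232.8 CPM, Cldn2 at 3.46 against 46.0 CPM, and Wfdc1, Opcml, Zic1 and Msx1 were each under 2 CPM. The anterior parts were removed, but surface epithelium-like cells were 18.2% of the NaIO3 library and 1.90% of the PBS library. That removal may therefore not have been complete. The cells of cluster 9 may come from the iris or ciliary epithelium or be RPE with more Pax6 RNA, and these values leave each of these open. A melanocyte origin was not tested and stays open too. With each library clustered alone, 177 NaIO3 cells were named melanocyte-like, and the best match of cluster 9 there had the same size (4.64% of 3813 cells). At a mitochondrial limit of 10%, 136 NaIO3 and 0 PBS cells were named melanocyte-like. The marker rule may thus name cells of cluster 9 melanocyte-like in some settings, but the overlap of cells was not tested. With 1 pool per group, the presence of cluster 9 in NaIO3 alone cannot be told apart from a difference in dissection.

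The Cdkn1a and Cdkn2a UMIs of NaIO3 RPE-like cells may come from free RNA, but these tests cannot exclude low expression in the cells themselves. Within a library a single source keeps its genes in a fixed ratio. Cdkn2a over 6 matrix genes of cluster 9 stood in RPE-like cells at 0.817 of its ratio in cluster 9 (0.688 to 0.965), so it was not above what those genes would bring. RPE-like cells that made Cdkn2a and matrix genes together at a low level would give a similar ratio, so this value cannot tell these cases apart. Cluster 9 was also not the only source. NaIO3 fibroblast-like cells held the 6 genes at 2188.5 CPM, which can lower the ratio and hide Cdkn2a made by RPE-like cells. Per 100 counts of the matrix genes there were 7.00 Cdkn2a counts in cluster 9, 5.72 in RPE-like, 7.97 in surface epithelium-like and 7.33 in macrophage-like cells. Cdkn1a in NaIO3 RPE-like cells was at 15.2% of the library mean (14.1 to 16.4), against a free RNA share of 16.8% estimated from other genes. In PBS RPE-like cells it was at 31.4% of the library mean against a share of 9.88%, so there that share does not account for it. The higher arrest median of NaIO3 RPE-like cells may come from free RNA, which differed between the libraries with their cell mix, and senescence below these levels was not tested.

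A mix of free RNA cannot pass the level of its sources. The cluster of 80 NaIO3 cells formed without the interferon list was compared with groups of at least 10 cells outside RPE-like and pigment-led cells. There 8 of 20 list members (Ifit1, Ifit3 and Rsad2 among them) stood by their lower bounds above every such group. These cells were still chosen on other interferon genes such as Mx1 and Iigp1. Without the named higher genes as well, 2 of 20 members, Ifit3 and Rsad2, stood above every such group, in a cluster of 659 NaIO3 cells. For both genes the highest such group was 13 endothelial-like cells, at 166.4 and 36.2 CPM, against lower bounds of 236.9 and 42.3 CPM. The counting error of so few cells was not taken into account, so the cluster of 659 cannot exclude free RNA. In the cluster of 80 the lower bounds were 2595 and 496 CPM. This argues against free RNA alone for Ifit3 and Rsad2 in those 80 cells, and for the other members it was not excluded. In RPE-like cells outside cluster 15 the median member stood at 30.9% of the library mean, against a free RNA share of 16.8%, and whether those cells expressed the genes themselves stays open. The interferon-led subcluster of RPE-like cells held 79 cells in NaIO3 and 0 in PBS, and a response to NaIO3 cannot be told apart from any other difference between the pools, with 1 library per group.

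Further values come from classes with too few PBS cells for a comparison. In macrophage-like cells (30 in PBS and 457 in NaIO3) resident macrophage genes had a median log2 ratio of -2.56 (1 of 7 above 1) but -0.61 for their summed counts, MHC class II genes -1.26 (0 of 5) and lysosomal genes 0.76 (13 of 15). In surface epithelium-like cells (80 and 695) interferon genes were at 1.06 (14 of 19 above 1; 0.61 for summed counts) and senescence arrest genes at 0.73 (10 of 11; 0.99 for summed counts). Members at the free RNA level were not assessed in these classes.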
